A study of Mus musculus with 27 samples.

How the data were processed

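RNA was measured in mouse embryonic fibroblasts of 3 lines, which were a wild-type line, a line without PKBalpha and a line in which, per the labels, PKBalpha had been put back into the knockout (called the line labelled R). PKBalpha is the protein kinase that Akt1 encodes. Each line was taken untreated, 4 h and 24 h after 10 Gy of gamma radiation, with 3 biological replicates per group per the labels, which gave 9 groups and 27 arrays. Per the labels' protocols the cells were female, at passage 45, grown with 10% serum and cultured for 24 h before irradiation. RNA was extracted with TRIZOL and labelled with biotin, per the same protocols, for Affymetrix arrays. Groups were taken from the sample titles, because the descriptions of 6 irradiated wild-type samples call them untreated. The labels do not say how long the untreated cells were kept, so time in culture and irradiation cannot be separated. Each genotype was represented by 1 line, so replicates measure the spread within a line and not between lines of 1 genotype.

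The deposited table holds linear intensity values for 45101 probe sets, 1 column per array, scaled by the authors so that the mean after trimming 2% of the values at each end was 500.003 on each array. The submitters' processing notes name RMA and GCRMA without versions or roles. The deposited values are on a linear scale, reach down to 0.00523 and up to 45330, and have array medians that differ, from 54.43 to 80, which is not the form that either method gives. The summary method is therefore not known. Intensities have no counting depth, so the number of arrays limits the precision.

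Values were taken to log2 without an offset and without further normalization. The 64 control probe sets were set aside. Of the others, 34945 carried 1 gene symbol, 932 carried several and 9160 carried none in the reference tables, and 34741 of the gene identifiers matched the RefSeq gene table. Each gene was represented by its brightest probe set over all arrays, which gave 18193 genes, of which 9010 had several probe sets. Genes without a probe set of a single symbol were not analysed. The background level was set at the highest of 243 values of 9 probe sets for Y-linked genes, which female cells lack, at an intensity of 48.3 (5.59 on the log2 scale). Where a group's mean lay below it, the fold was computed against the background level and is given as a lower bound. The spread between replicates depended on the level, with a median SD of 1.44 on the log2 scale in the dimmest 10% of genes and 0.18 in the brightest 10%.

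Differences were tested with limma 3.58.1 in R 4.3.3, with a model of 9 group means (18 residual degrees of freedom, 1.39 prior degrees of freedom) and moderated variances. The 15 contrasts were irradiated against untreated cells in each line and at each time, the untreated lines against each other, and the differences between lines in the response to irradiation. A gene was called changed at a Benjamini-Hochberg adjusted p below 0.05 within its contrast, two-sided. Of 39 gene lists, 36 with at least 5 measured members that were not label checks were tested against the other genes with limma's camera at a preset correlation of 0.01, and again with a correlation estimated for each list. List members were also counted with p values adjusted over the list alone. Group sizes of 3 against 3 allow no exact permutation p below 0.1, so no single-gene permutation tests were made.

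The gene lists, the contrasts, the threshold, the first set of alternatives and the rule for naming genes were fixed before the data were examined. The rule named Akt1 and Akt2 in each comparison and Cdkn1a, Mdm2 and Ccng1 in each irradiation comparison. It further named up to 10 genes with the largest change in each direction among those past the threshold, in 2-group contrasts only where all 3 arrays of a group lay beyond the other 3. It also named up to 4 members of each list with the smallest p in each contrast, and the members of the label-check lists. The text uses part of these.

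The alternatives fixed in advance were a block for the replicate number, a fit on the compared arrays only, an intensity trend in the prior variance, genes above the median level (7.26 on the log2 scale), quantile normalization, equal array medians, the mean of all probe sets of a gene, each probe set tested by itself, estimated correlations for the lists, the line R against the knockout in the irradiated arrays, response correlations over genes past the threshold in at least 1 of the 2 lines, and leaving out each array in turn. Replicate numbers did not pair the arrays of different groups. Over 108 pairs of arrays that share a number in different groups, the correlation of deviations from the group means ran from -0.79 to 0.83 with a median of 0.03, and 14 of 27 arrays correlated best, on average, with the arrays of their own number. A block was therefore used only as an alternative.

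After the data had been seen, 4 alternatives were added. These were the log2 ratio of each array's Gapdh 3' to 5' control probe sets as a covariate, a fit without the 5 arrays whose ratio was above -0.25, an offset of 32 before the log, and response correlations over genes above the median level without those 5 arrays. Genes shared between lines were recounted under the alternatives at that stage too. The test of wild-type cells at 4 h against untreated ones was tested on simulated data with each gene's own spread over 18193 genes. Among genes above the median level it recovered 75 of 100 made to differ by 1 on the log2 scale. It recovered 95 of 100 made to differ by 2, with 7 calls among 17993 other genes. Camera called the 1 shifted list and 0 of the other 35. The simulated genes varied independently of each other, so this cannot show the false calls of genes or lists where genes are correlated.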

Results

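Levels of messenger RNA were measured on 27 arrays, 3 for each of 9 groups. The groups were fibroblasts of the wild-type line, of the PKBalpha knockout and of the line labelled R, each untreated, 4 h and 24 h after 10 Gy of gamma radiation. The labels name untreated cells of each genotype as the reference, and the series asks how fibroblasts with and without PKBalpha respond to irradiation. The median intensity per array lay between 54.43 and 80, and between 10577 and 11682 of 18193 genes per array lay above the background level of 48.3. Differences are given on the log2 scale with the standard error of the model. Levels are geometric mean intensities of the 3 arrays of a group, and adjusted p values are from limma. The 3 arrays per group limit the precision of each value.

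The Gapdh control probe sets at the 3' and 5' ends of the transcript set 5 arrays apart. Their log2 ratios ran from -0.187 to 0.16, against -0.466 to -0.298 on the other 22 arrays, and their actin ratios from 0.39 to 0.592 against 0.128 to 0.292. The 5 arrays were replicate 2 of untreated wild-type cells, replicate 0 of wild-type cells at 4 h, replicate 2 of untreated knockout cells, replicate 1 of the untreated line R and replicate 2 of the line R at 24 h. Each untreated group thus held 1 such array. The first principal component, with 51.9% of the variance, separated wild-type arrays from those of both other lines. The second component, with 17%, separated 4 of the 5 arrays from all others. Counts without these 5 arrays, an alternative added after the data had been seen, stand beside the counts below.

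**Figure D1:**
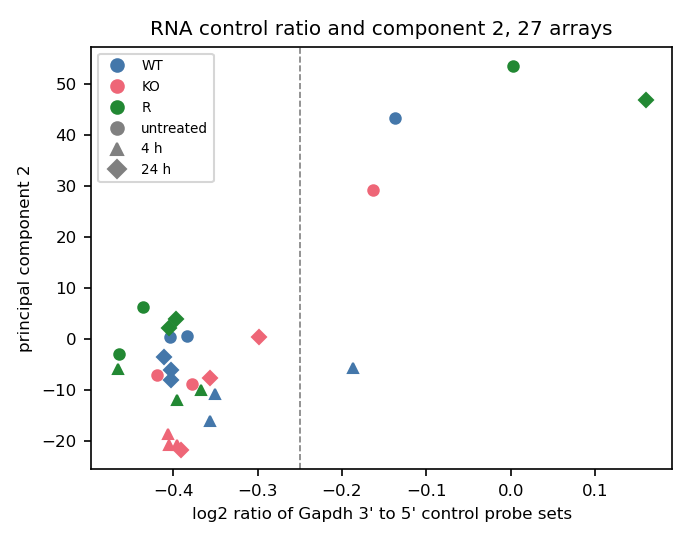
Each symbol is 1 of the 27 arrays, with the log2 ratio of the Gapdh 3' to 5' control probe sets on the horizontal axis and the second principal component on the vertical axis, coloured by line and shaped by time. The dashed line marks -0.25, which 5 arrays exceed, and 4 of these 5 lie above all others on the second component.

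Akt1, the gene removed in the knockout, read 3550 in wild-type cells by its brightest probe set (geometric mean of 9 arrays, 2980 to 4550). It read 21.5 in knockout cells (2.35 to 65.5) and 21 in the line labelled R (6.25 to 41.9). In untreated cells it was at least 73.1-fold lower in the knockout than in the wild type (adjusted p = 1.4e-06) and at least 73.1-fold lower in the line labelled R (adjusted p = 3e-06). The untreated line R and the untreated knockout both lay below background (adjusted p = 0.86). A second probe set read 2260, 5.56 and 50.7 in the same order. In untreated cells it read 55.8 in the line labelled R, near background, and 2.36 in the knockout, below it (adjusted p = 0.0053 over probe sets). Another probe set read 124, 47 and 52.2 (R against the knockout in untreated cells, adjusted p = 0.96 over probe sets), and the last one lay below background in all lines (7.26, 9.65 and 6.97). The Akt1 transcript was therefore not at the wild-type level in the line labelled R by any of the 3 probe sets that read above background in the wild type. Where the probe sets lie relative to the reintroduced sequence is not known. Akt2, which encodes the related kinase PKBbeta, read 864 in untreated wild-type cells, 768 in the knockout (-0.17 ± 0.14, adjusted p = 0.48) and 801 in the line labelled R (-0.11 ± 0.14 against the wild type, adjusted p = 0.68). With the mean of its 3 probe sets both differences passed (-0.60 with adjusted p = 0.021 and -0.61 with 0.019), and over the alternatives the adjusted p ran from 0.021 to 0.91 and from 0.019 to 0.96. Neither Akt1 nor Akt2 passed the threshold in the 6 irradiation comparisons, where the smallest adjusted p was 0.55 for Akt1 and 0.44 for Akt2. Xist, which is transcribed from the inactive X chromosome of female cells, read 11000 in wild-type and 6980 in knockout cells (-0.66 ± 0.17, adjusted p = 0.0074, 0.0023 to 0.092 over the alternatives, the highest on the compared arrays only). Of the INK4 locus genes, Cdkn2a (-0.20, adjusted p = 0.78) and Cdkn2b (0.22, adjusted p = 0.41) did not pass the threshold between untreated knockout and wild-type cells.

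**Figure D2:**
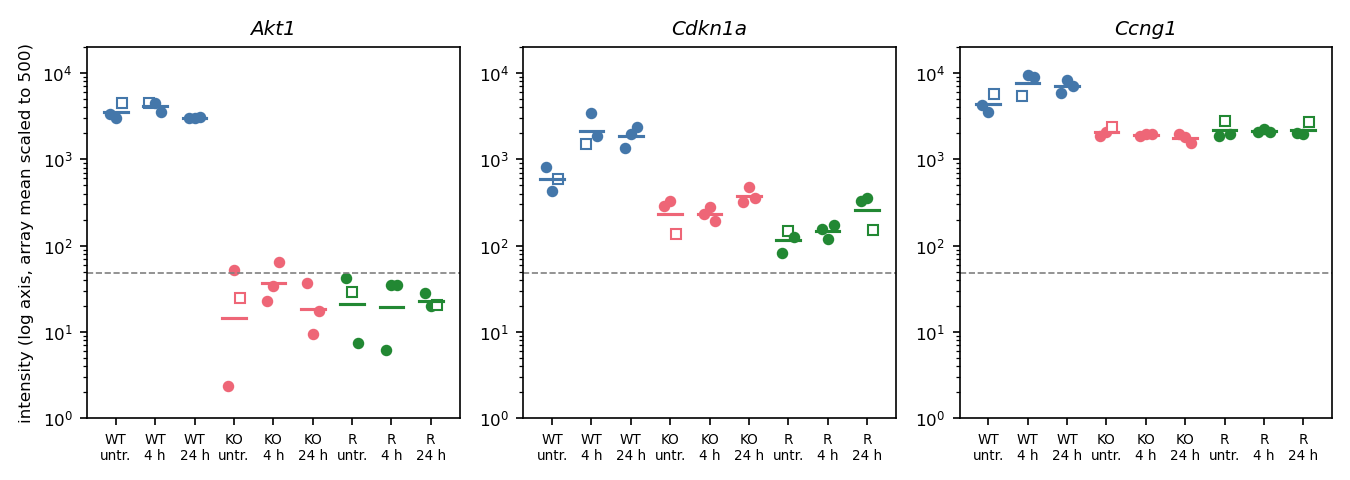
Points are intensities of Akt1, Cdkn1a and Ccng1 on the 27 arrays on a log axis, in replicate order from left to right within each group, with the 5 arrays of high Gapdh ratio as open squares. Bars are geometric means of 3 arrays and the dashed line is the background level of 48.3, below or near which Akt1 lies in the knockout and in the line labelled R.

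In the wild-type line at 4 h, targets of p53, the transcription factor that DNA damage activates, rose. Cdkn1a, which encodes the cell cycle inhibitor p21, rose from 592 to 2130 (1.85 ± 0.39, adjusted p = 0.015). Ccng1, which encodes cyclin G1, rose from 4400 to 7770 (0.82 ± 0.22, adjusted p = 0.045). Phlda3, an inhibitor of Akt signalling, rose by 0.91 ± 0.18 and Ei24 by 0.83 ± 0.18. Mdm2, the ubiquitin ligase of p53, read 2530 against 983 and did not pass the threshold (1.36 ± 0.53, adjusted p = 0.18, 0.0097 without the 5 arrays, 0.0071 to 0.53 over the alternatives). A second probe set of Mdm2 rose by 1.13 (adjusted p = 0.044 over probe sets, 0.26 for the first), the remaining one did not pass (-0.90, 0.64), a second one of Cdkn1a by 1.84 (0.013), and the 3 of Ccng1 did not pass over probe sets (0.095, 0.42 and 0.16). Of 32 measured p53 targets 7 rose and 1 fell over all genes, and 8 rose and 1 fell when adjusted over the list alone. The list rose with a median of 0.47 (adjusted p = 1e-06, and adjusted p = 0.03 with an estimated correlation). Genes of DNA synthesis and repair rose too. Exo1, an exonuclease of DNA repair, rose by 1.24 ± 0.15 (adjusted p = 0.00087), and Rrm2, a subunit of ribonucleotide reductase, by 1.13 ± 0.16. The replication factor gene Mcm10 rose by 1.08 ± 0.15 and Brca1, which acts in homologous recombination, by 0.90 ± 0.11.

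Among the lists for the cell cycle and DNA repair in wild-type cells at 4 h, S phase and E2F genes rose with a median of 0.59 (10 of 31 members over all genes, 19 adjusted over the list alone, adjusted p = 2.1e-16, and adjusted p = 0.023 with an estimated correlation). Homologous recombination genes rose by 0.49 (5 of 17, 12 adjusted over the list alone, adjusted p = 0.00027 with an estimated correlation). G2/M genes, which act at entry into and passage through mitosis, had 5 of 35 members higher, and 21 adjusted over the list alone. Among these were Top2a (0.66 ± 0.13) and the spindle checkpoint kinases Bub1 (0.68 ± 0.17) and Ttk (0.53 ± 0.12). Their list rose by 0.45 (adjusted p = 6.9e-13), a call lost with an adjusted p = 0.076 with an estimated correlation. Break sensing and end joining genes rose by 0.30 (1 of 19, 2 adjusted over the list alone, adjusted p = 0.03 with an estimated correlation). Immediate early genes rose by 0.45 (2 of 18, 7 adjusted over the list alone, adjusted p = 0.03 with an estimated correlation). Myc, which encodes a growth-promoting transcription factor, rose by 0.86 (adjusted p = 0.039, 0.21 without the 5 arrays, 0.0085 to 0.37 over the alternatives). When the 5 arrays were left out, the adjusted p with an estimated correlation was 0.012 for p53 targets, 0.018 for S phase and E2F genes, 0.0035 for homologous recombination, 0.018 for break sensing and 0.16 for immediate early genes.

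Lipid synthesis and matrix genes fell in the wild-type line at 4 h. All 20 measured genes of cholesterol synthesis had a negative difference, of which 12 fell over all genes and 20 adjusted over the list alone. Their median fell by 0.85 (adjusted p = 2.1e-20, and adjusted p = 0.014 with an estimated correlation). Lanosterol synthase (Lss) fell from 2270 to 1030 (-1.14 ± 0.22) and Dhcr7, which catalyses the last step of the pathway, from 642 to 307 (-1.07 ± 0.18). Squalene epoxidase (Sqle) fell from 6020 to 3710 (-0.70 ± 0.12). Of 14 fatty acid synthesis genes 4 fell, 5 adjusted over the list alone (median -0.50, adjusted p = 6e-04 with an estimated correlation). The desaturase Scd1 changed by -0.88 ± 0.14 and the elongase Elovl6 by -0.77 ± 0.13. Extracellular matrix genes fell by 0.52 (7 of 26, 14 adjusted over the list alone, adjusted p = 0.03 with an estimated correlation). Periostin (Postn) fell from 4060 to 1140 and Mmp3, a matrix-degrading protease, from 8490 to 2400. Lysosome genes fell by 0.55 (5 of 18, 11 adjusted over the list alone, adjusted p = 0.03 with an estimated correlation). Among them was the sialidase gene Neu1 (-0.85, adjusted p = 0.015, 0.12 without the 5 arrays, 0.0037 to 0.5 over the alternatives). The medians without the 5 arrays were -0.67 for cholesterol synthesis (3 genes lower) and -0.35 for lysosome genes, with adjusted p values of 0.071 and 0.09 with an estimated correlation. The same adjusted p was 0.027 for fatty acid synthesis and 0.036 for extracellular matrix. Replicate 0 at 4 h, 1 of the 5 arrays, had the lowest cholesterol synthesis mean of the group, -1.215 against the mean of the untreated arrays.

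Limma called 592 genes changed in wild-type cells at 4 h, 275 higher and 317 lower, 212 of them by over 2-fold and 48 with both groups below background. All 3 arrays of a group lay beyond the other 3 in 21.2% of genes, where chance gives 10%. The fit without the 5 arrays called 366 genes, 236 higher and 130 lower, 220 of them shared with the 592. Of 23 genes named for this comparison as past the threshold, 13 passed with the mean of all probe sets and 19 without the 5 arrays. That mean gave an adjusted p of 0.1 for Ccng1, 0.32 for Exo1, 0.23 for Mcm10, 0.18 for Brca1, 0.16 for Ttk, 0.06 for Myc, 0.13 for Elovl6, 0.5 for Neu1, 0.79 for Zfp367 and 0.082 for Megf6, and the fit without the 5 arrays gave 0.098 for Lss and 0.064 for Megf6. Equal array medians gave 0.076 for Bub1, 0.061 for Sqle and 0.078 for Scd1. The ranges over the alternatives were 0.0016 to 0.43 (Ccng1), 0.00017 to 0.33 (Mcm10), 7.9e-05 to 0.33 (Brca1), 0.0047 to 0.37 (Ttk), 0.00079 to 0.33 (Elovl6), 0.0019 to 0.33 (Lss), 0.0059 to 0.33 (Megf6), 0.001 to 0.33 (Bub1), 0.00094 to 0.33 (Sqle) and 0.00024 to 0.33 (Scd1). The count was 367, 288 and 302 without replicates 0, 1 and 2 of the untreated cells, and 190 and 301 without replicates 0 and 1 at 4 h. It was 0 (2081 at an unadjusted p under 0.05) when limma was fitted to the 6 compared arrays alone. With equal array medians, which moved the median of all genes by 0.131, 230 genes were higher and 116 lower.

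At 24 h fewer genes were called in the wild-type line than at 4 h. Elovl6 fell from 2540 to 1400 (-0.86 ± 0.13, adjusted p = 0.011) and the transcription factor gene Ebf3 from 375 to 174 (-1.10 ± 0.16, adjusted p = 0.011). Cgas, which encodes a sensor of cytosolic DNA, fell from 225 to 87.8 (-1.36 ± 0.24, adjusted p = 0.031). Zfp367 rose from 412 to 746 (0.86 ± 0.14, adjusted p = 0.017) and Macir from 161 to 340 (1.08 ± 0.17, adjusted p = 0.014). Cdkn1a read 1860 against 592 (1.65 ± 0.39, adjusted p = 0.15), Ccng1 6990 against 4400 (0.67 ± 0.22, adjusted p = 0.38) and Mdm2 2210 against 983 (1.17 ± 0.53, adjusted p = 0.5), none past the threshold with all arrays. Ccng1 passed without the 5 arrays (0.86, adjusted p = 0.036, 0.036 to 0.79 over the alternatives). Of 32 p53 targets 30 had a positive difference and 5 were higher adjusted over the list alone, none over all genes. The list rose (median 0.26, adjusted p = 1.1e-05), with an adjusted p = 0.09 with an estimated correlation. All 20 cholesterol synthesis genes had a negative difference (median -0.46, 8 lower adjusted over the list alone, adjusted p = 8.4e-13, and adjusted p = 0.061 with an estimated correlation). Fatty acid synthesis fell (median -0.35, 1 of 14 lower, also 1 adjusted over the list alone) and immediate early genes rose (median 0.43, 4 of 18 adjusted over the list alone), with adjusted p values of 0.00096 and 0.019 with an estimated correlation.

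In all, 9 genes were called at 24 h in the wild type, 4 higher and 5 lower, 4 of which lay below background in both groups, with 1745 genes at an unadjusted p under 0.05. The groups were separated in 15.8% of genes, where chance gives 10%. The fit without the 5 arrays called 13 genes, 2 of them shared with the 9. In that fit the adjusted p was 0.046 for Elovl6, 0.084 for Ebf3, 0.12 for Cgas, 0.071 for Zfp367 and 0.097 for Macir. Over the alternatives these ran from 0.0023 to 0.68 for Elovl6, 0.0023 to 0.5 for Ebf3, 0.0082 to 0.76 for Cgas, 0.0033 to 0.73 for Zfp367 and 0.0028 to 0.25 for Macir. The count was 15 without replicate 1 of the untreated cells, 23 and 3 without replicates 0 and 1 at 24 h, and 0 (1139 at an unadjusted p under 0.05) when limma was fitted to the 6 compared arrays alone.

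In the knockout at 4 h the p53 target genes named for the wild type did not pass the threshold. Cdkn1a read 234 against 235 (-0.01 ± 0.39, adjusted p = 1), Ccng1 1930 against 2090 (-0.11 ± 0.22, adjusted p = 0.88) and Mdm2 845 against 570 (0.57 ± 0.53, adjusted p = 0.7). The median of the 32 p53 targets was -0.16 (none called over all genes, 1 higher and 4 lower adjusted over the list alone, adjusted p = 0.12). Immediate early genes rose with a median of 0.62 (2 of 18, 7 adjusted over the list alone, adjusted p = 9.9e-09, and adjusted p = 0.0043 with an estimated correlation). The transcription factor genes Nr4a1 (314 to 772, 1.30 ± 0.25) and Jun (1040 to 2170, 1.07 ± 0.2) rose. So did Id2 (211 to 703, 1.74 ± 0.37) and Tnfaip3, an inhibitor of NF-kappaB signalling (1.13 ± 0.2). S phase and E2F genes rose by 0.42 (1 of 31, 11 adjusted over the list alone, adjusted p = 4.7e-13), a call with an adjusted p = 0.06 with an estimated correlation. Homologous recombination genes rose by 0.32 (1 of 17, 6 adjusted over the list alone, adjusted p = 0.0044 with an estimated correlation, 0.069 without the 5 arrays), and Exo1 rose from 865 to 1510. Replicate 2 of the untreated knockout, 1 of the 5 arrays, had the lowest mean of S phase and E2F genes of its group, -0.268 against the group mean. In the fit without the 5 arrays the median rise was 0.28.

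Among the genes that fell in the knockout at 4 h were Abca1, a cholesterol exporter (714 to 236, -1.60 ± 0.34), Bmp4, a growth factor of the TGF-beta family (802 to 311, -1.37 ± 0.29), and Tgfbi, a matrix protein induced by TGF-beta (6740 to 3390, -0.99 ± 0.2). Angpt4 was at least 7.14-fold lower. Extracellular matrix genes had a median of -0.33 (10 of 26 lower adjusted over the list alone, none over all genes, adjusted p = 6.1e-08, and adjusted p = 0.086 with an estimated correlation). The cholesterol synthesis list was not called (median -0.05, adjusted p = 0.92). Limma called 67 genes, 27 higher and 40 lower, 38 by over 2-fold and 4 with both groups below background. In all, 24.4% of genes were separated, where chance gives 10%. The fit without the 5 arrays called 166 genes, 80 higher and 86 lower, 40 of them shared with the 67. With the mean of all probe sets 3 of the 11 genes named for this comparison as past the threshold passed again. Id2 (adjusted p = 0.053), Exo1 (0.052), Bmp4 (0.067) and Angpt4 (0.07) were not among the 166. Over the alternatives these ran from 0.011 to 0.18, 0.0072 to 0.52, 0.011 to 0.16 and 0.011 to 0.15. They ran from 0.0071 to 0.16 for Nr4a1, 0.0071 to 0.12 for Jun, 0.0066 to 0.16 for Tnfaip3, 0.011 to 0.57 for Abca1 and 0.009 to 0.14 for Tgfbi. The count was 2, 3 and 18 without replicates 0, 1 and 2 of the untreated cells. It was 1, 0 and 3 without replicates 0, 1 and 2 at 4 h (1886 at an unadjusted p under 0.05 where it was 0), 20 with equal array medians (14 higher and 6 lower), and 0 (2358 unadjusted) when limma was fitted to the 6 compared arrays alone.

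At 24 h limma called 0 genes in the knockout, with 1064 at an unadjusted p under 0.05. The groups were separated in 12.1% of genes, where chance gives 10%. Nr4a1 read 938 against 314 (1.58 ± 0.25, adjusted p = 0.078, 0.011 among genes above the median level, 0.011 to 0.4 over the alternatives), Cdkn1a 380 against 235 (0.69 ± 0.39, adjusted p = 0.88). Ccng1 (-0.24) and Mdm2 (0.54) had an adjusted p of 0.92. Immediate early genes rose as a list (median 0.59, 6 of 18 adjusted over the list alone, none over all genes, adjusted p = 6.6e-10, and adjusted p = 0.0018 with an estimated correlation). The p53 targets were not called (median -0.06, adjusted p = 0.68). Leaving out the 5 arrays gave 6 genes, and 5, 6 and 3 genes were called without replicate 1 or 2 of the untreated cells or replicate 1 at 24 h.

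In the line labelled R at 4 h the same 3 p53 target genes did not pass the threshold either. Cdkn1a read 147 against 115 (0.35 ± 0.39, adjusted p = 0.73), Ccng1 2120 against 2160 (-0.03 ± 0.22, adjusted p = 0.97) and Mdm2 598 against 439 (0.45 ± 0.53, adjusted p = 0.75). The p53 list was not called (median -0.05, mean 0.11, 1 of 32 higher and 1 lower, 2 and 2 adjusted over the list alone, adjusted p = 0.99). Rrm2b, a p53-induced subunit of ribonucleotide reductase, rose by 0.64 (adjusted p = 0.026, 0.069 without the 5 arrays, 0.0062 to 0.44 over the alternatives). Immediate early genes rose with a median of 0.58 (2 of 18, 9 adjusted over the list alone, adjusted p = 6.6e-07, and adjusted p = 0.014 with an estimated correlation, 0.11 without the 5 arrays). Fosl1, a partner of Jun in the AP-1 transcription factor, rose from 462 to 1790 (1.96 ± 0.41) and Jun from 948 to 1760 (0.89, adjusted p = 0.042). Dusp6, a phosphatase that acts on ERK kinases, rose from 111 to 307 (1.47 ± 0.28). S phase and E2F genes rose by 0.50 (12 of 31 adjusted over the list alone, none over all genes, adjusted p = 7.8e-13, and adjusted p = 0.084 with an estimated correlation). Replicate 1 of the untreated line R, 1 of the 5 arrays, had the lowest mean of S phase and E2F genes of its group, -0.331 against the group mean. In the fit without the 5 arrays the median rise was 0.35.

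G2/M genes fell as a list in the line labelled R at 4 h (median -0.20, 2 of 35, 5 adjusted over the list alone, adjusted p = 0.022), a call with an adjusted p = 0.62 with an estimated correlation. Cdc20, which activates the anaphase-promoting complex, fell from 5390 to 3030 (-0.83, adjusted p = 0.028, 0.061 without the 5 arrays, 0.0067 to 0.36 over the alternatives) and the centromere protein gene Cenpf from 1860 to 1130 (adjusted p = 0.042, 0.011 to 0.41 over the alternatives). The largest falls above background included Sorbs2, a cytoskeletal adaptor (782 to 184, -2.09 ± 0.36), Megf6 (494 to 163, -1.60 ± 0.24), Tgfbi (3040 to 1310, -1.22 ± 0.2) and the imprinted gene Peg3 (1360 to 615, -1.15 ± 0.17). The calls of Sorbs2 (adjusted p = 0.012, 0.0017 to 0.33 over the alternatives) and Peg3 (0.0063, 0.00086 to 0.6) were lost with the mean of all probe sets. Of 12 genes named for this comparison as past the threshold, 4 passed with that mean and 6 without the 5 arrays. Extracellular matrix genes had a median of -0.38 (7 of 26 lower adjusted over the list alone, none over all genes, adjusted p = 3.7e-06, and adjusted p = 0.21 with an estimated correlation). Cholesterol synthesis was not called (median -0.08, adjusted p = 0.71). Limma called 178 genes, 51 higher and 127 lower, 79 by over 2-fold and 10 with both groups below background. In all, 20.7% of genes were separated, where chance gives 10%. The fit without the 5 arrays called 80 genes, 29 higher and 51 lower, 48 of them shared with the 178. Fosl1 (adjusted p = 0.053), Jun (0.11) and Dusp6 (0.076) were not among these, and over the alternatives ran from 0.0069 to 0.41, 0.011 to 0.45 and 0.0038 to 0.41. The count was 388, 15 and 11 without replicates 0, 1 and 2 of the untreated cells and 13, 69 and 26 without replicates 0, 1 and 2 at 4 h. It was 35 with equal array medians, and 0 (1782 at an unadjusted p under 0.05) when limma was fitted to the 6 compared arrays alone.

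At 24 h limma called 0 genes in the line labelled R, with 830 at an unadjusted p under 0.05. In all, 9.05% of genes were separated, where chance gives 10%. Cdkn1a read 261 against 115 (1.18 ± 0.39, adjusted p = 0.91). Ccng1 (0.03) and Mdm2 (0.09) had an adjusted p of 1. The p53 targets were not called (median 0.11, mean 0.29, 22 of 32 positive, none called over all genes or over the list alone, adjusted p = 0.073, 0.13 with the Gapdh covariate, 0.035 without the 5 arrays, and 0.45 with an estimated correlation). The list mean was 0.28, 0.283 and 0.305 on the 3 arrays at 24 h against the mean of the untreated ones, which ran from -0.099 to 0.073. All 18 immediate early genes had a positive difference and the list rose (median 0.55, 2 adjusted over the list alone, none over all genes, adjusted p = 5.8e-11, and adjusted p = 0.001 with an estimated correlation, 0.08 without the 5 arrays). Cholesterol synthesis fell (median -0.31, 2 of 20 lower adjusted over the list alone, none over all genes, adjusted p = 1.6e-09, and adjusted p = 0.16 with an estimated correlation). Fatty acid synthesis fell by 0.16 (1 of 14 adjusted over the list alone, none over all genes, adjusted p = 0.011 with an estimated correlation). Leaving out the 5 arrays gave 1 gene, and 2 genes were called without replicate 0 or 2 of the untreated cells.

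**Figure D3:**
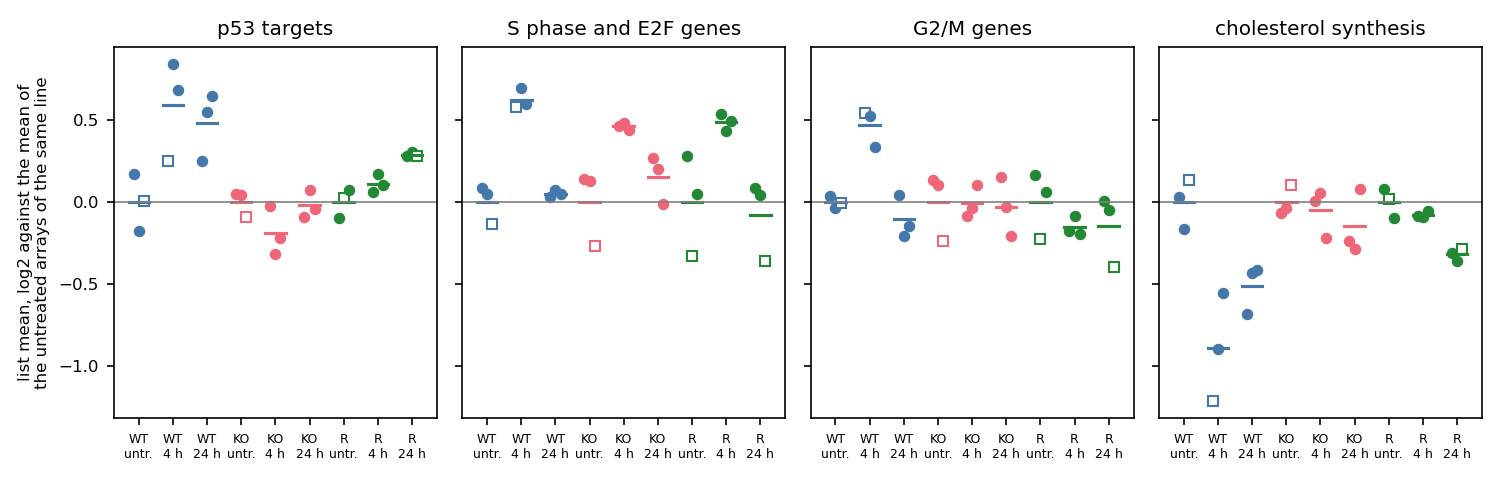
Points are the mean log2 level of 4 gene lists on each of the 27 arrays against the mean of the untreated arrays of the same line, in replicate order from left to right within each group, with bars for group means and open squares for the 5 arrays of high Gapdh ratio. At 4 h p53 targets and G2/M genes lie higher, and cholesterol synthesis lower, on the wild-type arrays, while S phase and E2F genes lie higher in all 3 lines.

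Whether the lines differed in their response was tested by the difference of responses itself. At 4 h the response of p53 targets was lower in the knockout than in the wild type, with 31 of 32 members negative and a median of -0.69 (6 lower adjusted over the list alone, none over all genes, adjusted p = 3e-12, and adjusted p = 0.0074 with an estimated correlation). The difference was -1.86 ± 0.55 for Cdkn1a (adjusted p = 0.54), -0.93 ± 0.31 for Ccng1 (0.64, 0.034 without the 5 arrays, 0.034 to 0.95 over the alternatives) and -0.80 ± 0.75 for Mdm2 (1), so none of these genes passed the threshold over all arrays. All 20 cholesterol synthesis genes had a positive difference between the responses of the knockout and the wild type, with a median of 0.83 (15 higher adjusted over the list alone, none over all genes, adjusted p = 1.1e-23, and adjusted p = 0.0074 with an estimated correlation, 0.083 without the 5 arrays). Fatty acid synthesis differed by 0.31 (14 of 14 positive, 1 adjusted over the list alone, adjusted p = 0.0042 with an estimated correlation, 0.083 without the 5 arrays). The 35 G2/M genes were all negative (median -0.48, 1 lower adjusted over the list alone, none over all genes, adjusted p = 2.3e-15, and adjusted p = 0.11 with an estimated correlation).

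Between the line labelled R and the wild type at 4 h, G2/M genes (median -0.65, 35 of 35 negative, 18 lower adjusted over the list alone), cholesterol synthesis (0.75, 20 of 20 positive, 13 higher adjusted over the list alone) and homologous recombination (-0.35, 14 of 17 negative, none adjusted over the list alone) differed with adjusted p values of 0.042, 0.013 and 0.013 with an estimated correlation. None of these members passed over all genes. The p53 list differed by -0.58 (26 of 32 negative, 9 lower adjusted over the list alone, none over all genes, adjusted p = 9.3e-07), with an adjusted p = 0.051 with an estimated correlation. The differences were -1.49 ± 0.55 for Cdkn1a (0.66), -0.85 ± 0.31 for Ccng1 (0.66) and -0.92 for Mdm2 (1). Between the line labelled R and the knockout no list call at 4 h held with an estimated correlation, where the smallest adjusted p was 0.5. Cdkn1a (0.36), Ccng1 (0.09) and Mdm2 (-0.12) had adjusted p values of 1. At 24 h the p53 list differed by -0.40 between the knockout and the wild type (28 of 32 negative, none adjusted over the list alone, adjusted p = 3.7e-06, and adjusted p = 0.14 with an estimated correlation). Cdkn1a (-0.96), Ccng1 (-0.90) and Mdm2 (-0.63) had adjusted p values of 1. In the line labelled R against the wild type at 24 h these genes differed by -0.47, -0.63 and -1.08 (adjusted p = 0.99 each), and against the knockout by 0.48, 0.27 and -0.45 (1 each).

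Few single genes passed the test of a response difference. Limma called 2 genes for the knockout against the wild type at 4 h and 1 at 24 h. It called 0 for the line labelled R against the knockout at 4 h (537 at an unadjusted p under 0.05) and 1 at 24 h, and 3 for the line labelled R against the wild type at 4 h and 1 at 24 h. Of the genes called, C430042M11Rik, D630004K10Rik and Ang3 lay below or near background in all groups concerned, and with the offset of 32 each of their calls was lost (adjusted p from 0.1 to 1). The others were Nkd1 and Sorbs2. Nkd1, an inhibitor of Wnt signalling, read 43.1 against 21.3 in the line labelled R and 88.1 against 359 in the wild type (3.04 ± 0.44, adjusted p = 0.012, 0.00014 to 0.87 over the alternatives), with both groups of the line labelled R below background. With levels below background set to it the difference was 2.03, and the call was lost with the mean of all probe sets (0.87). Sorbs2 read 184 against 782 in the line labelled R and 57.7 against 26.5 in the wild type (-3.21 ± 0.5, adjusted p = 0.022, 0.11 without the 5 arrays, 0.0048 to 1 over the alternatives). Untreated wild-type cells lay below background, and with their level set to it the difference was -2.35. Leaving out the 5 arrays gave counts in the same order of 19, 0 (932 unadjusted), 0 (796 unadjusted), 4, 9 and 3. Single arrays moved these counts. For the knockout against the wild type at 4 h the count was 1, 4 and 8 without replicates 0, 1 and 2 of untreated wild-type cells, 1 and 4 without replicates 0 and 2 of wild-type cells at 4 h, 4 without replicate 1 or 2 of the untreated knockout and 1 without replicate 1 of the knockout at 4 h. At 24 h it was 2 without replicate 1 of untreated wild-type cells, 3 without replicate 0 or 2 of wild-type cells at 24 h, and 6 without replicate 1 of the untreated knockout. It was 3 and 0 (636 unadjusted) without replicates 1 and 2 of the knockout at 24 h. For the line labelled R against the knockout at 4 h it was 2 without replicate 2 of the knockout at 4 h. It was 1 without replicate 2 of the untreated knockout, replicate 0 of the knockout at 4 h, replicate 0 of the untreated line R or any replicate of the line R at 4 h. At 24 h it was 2 without replicate 2 of the untreated line R or replicate 1 of the line R at 24 h. It was 0 (504 to 795 unadjusted) without replicate 1 or 2 of the untreated knockout, replicate 0 of the knockout at 24 h, replicate 0 or 1 of the untreated line R, or replicate 0 or 2 of the line R at 24 h. For the line labelled R against the wild type at 4 h it was 5 without replicate 2 of untreated wild-type cells, and 1 and 6 without replicates 0 and 2 of wild-type cells at 4 h. At 24 h it was 4 and 0 (593 unadjusted) without replicates 1 and 2 of untreated wild-type cells, and 2 without replicate 2 of wild-type cells at 24 h.

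Across the lines, 16 genes changed in all 3 lines at 4 h, 5 higher and 11 lower. Without the 5 arrays 14 did, 3 of them among the 16, and over the other alternatives the number ran from 0 on the compared arrays only to 117 above the median level. It was 6 to 14 without single arrays of the wild type, 1 without replicate 2 of the untreated knockout and 0 without any other knockout array. It was 28 without replicate 0 of the untreated line R and 3 to 8 without any other array of that line. Exo1 rose by 1.24, 0.80 and 0.77 in the wild type, the knockout and the line labelled R, and Zfp367 by 0.89, 0.86 and 0.89. With the mean of all probe sets Zfp367 lost its call in each line (adjusted p = 0.79, 0.51 and 0.49) and Exo1 in the knockout (0.52) and the line labelled R (0.92). Over the alternatives the adjusted p of Zfp367 ran from 0.00045 to 0.79, 0.0038 to 0.51 and 0.00097 to 0.49, and that of Exo1 from 5.2e-05 to 0.33, 0.0072 to 0.52 and 0.0063 to 0.92. Tgfbi fell by 1.38, 0.99 and 1.22, and Megf6 by 1.05, 1.31 and 1.60. Their adjusted p ran from 0.00024 to 0.33, 0.009 to 0.14 and 0.0016 to 0.3, and from 0.0059 to 0.33, 0.0066 to 0.13 and 0.00086 to 0.27, over the alternatives. Genes changed in the same direction numbered 23 in the knockout and the wild type, 36 in the line labelled R and the knockout, and 69 in the line labelled R and the wild type. Without the 5 arrays these were 30, 29 and 19, of which 5, 8 and 10 were among the former. Single arrays left out gave 0 to 21, 0 to 65 and 4 to 126, where 65 and 126 were found without replicate 0 of the untreated line R, 21 without replicate 2 of untreated wild-type cells, 0 for both pairs without replicate 0 of the knockout at 4 h, and 4 without replicate 0 of the line R at 4 h. At random 1.11, 0.355 and 2.98 would be shared, and 0 of the genes that limma called in both lines changed in opposite directions. Across all genes, which are not independent replicates, the responses at 4 h correlated at 0.15, 0.18 and 0.14 in the same order, and at 0.69, 0.84 and 0.69 over genes above the median level. Without the 5 arrays they were 0.09, 0.12 and 0.08, and above the median level 0.53, 0.76 and 0.52. The lowest values with 1 array left out were 0.1 and 0.09 for the knockout and R against the wild type without replicate 2 of untreated wild-type cells, 0.09 for the latter also without replicate 1 of the untreated line R, and 0.12 for R and the knockout without that array.

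**Figure D4:**
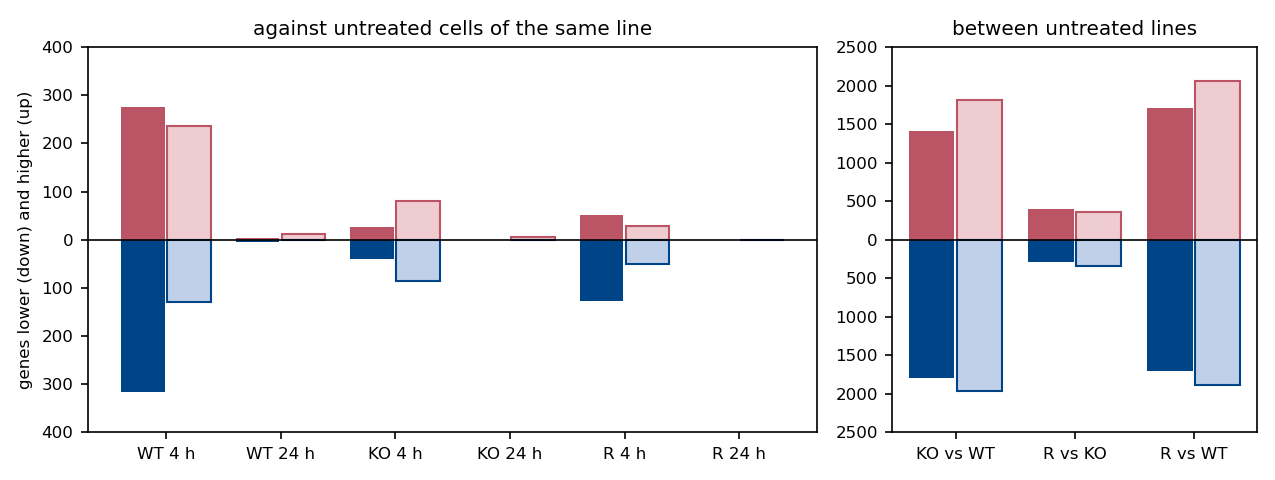
Bars count genes higher (up) and lower (down) at an adjusted p below 0.05, for irradiated against untreated cells of each line on the left and for untreated lines on the right, on different vertical scales. Dark bars are from all 27 arrays and light bars from the fit without the 5 arrays of high Gapdh ratio, for example 592 and 366 genes for the wild type at 4 h.

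Both other untreated lines differed from the untreated wild type in more genes (3202 and 3418) than irradiated cells from untreated ones in any line (at most 592). In untreated knockout cells Upk3b, a uroplakin that also marks mesothelium, was at least 339-fold lower than in the wild type (18.8 against 16400, adjusted p = 3.3e-08). Aldh1a1, a retinaldehyde dehydrogenase, was at least 57.8-fold lower. Rpl39l, a paralog of the ribosomal protein gene Rpl39, was at least 148-fold higher (7150 against 19.5), Tnmd, a tendon marker, at least 71.5-fold higher and the transcription factor gene Zic1 at least 59.1-fold higher. Of 33 HOX genes, which encode position along the body axis, 9 were higher and 10 lower (9 and 11 adjusted over the list alone). Hoxc8 was at least 68.5-fold and Hoxc9 at least 37.8-fold higher, and Hoxa3 (-2.28 ± 0.16) and Hoxa5 (-2.33 ± 0.21) were lower. Of 21 imprinted genes 2 were higher and 5 lower (2 and 6 adjusted over the list alone). The growth factor gene Igf2 was lower (83 against 12600, -7.25 ± 0.53), and Grb10, an adaptor that inhibits insulin signalling, was at least 81.5-fold lower. The amino acid transporter gene Slc38a4 was higher (2810 against 227, 3.63 ± 0.39). Neither list was called as shifted one way (adjusted p = 0.78 and 0.24).

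Matrix, cell cycle and cell type genes also differed between untreated knockout and wild-type cells. Loxl1, a crosslinker of elastin, was lower (708 against 7940, -3.49 ± 0.2) and Col6a3, a collagen VI chain, higher (10300 against 1760, 2.55 ± 0.22), among 6 matrix genes higher and 5 lower of 26 (8 and 5 adjusted over the list alone). G2/M genes were higher as a list (median 0.40, 9 of 35, 10 adjusted over the list alone, adjusted p = 1.3e-06), as were ribosome biogenesis genes (0.36, 5 of 21, 6 adjusted over the list alone). Both calls had an adjusted p = 0.73 with an estimated correlation. Ttk was higher by 1.01 ± 0.12. Of 17 epithelial markers 4 were lower (also 4 adjusted over the list alone), with Krt7 at least 10.2-fold and Krt14 at least 14.9-fold lower. Of 14 smooth muscle markers 2 were higher and 2 lower (4 and 4 adjusted over the list alone), with Myl9 higher (10400 against 745) and calponin (Cnn1) lower (154 against 1300). In all 9 groups 10 of 18 macrophage markers and 12 of 16 endothelial markers lay below background. In the PI3K and AKT pathway list 1 of 19 genes was higher and 3 lower (the same numbers adjusted over the list alone, list adjusted p = 0.44). Phlpp1, an Akt phosphatase, was 1.08 ± 0.13 higher, and Pik3cb, which encodes a catalytic subunit of PI3 kinase, was lower (-1.47 ± 0.22, adjusted p = 4.6e-05, 8.6e-06 to 0.053 over the alternatives). Of the FOXO targets, Fbxo32, an atrophy-related ubiquitin ligase, was 3.09 ± 0.43 higher. The p53 targets Cdkn1a (235 against 592, -1.33 ± 0.39, adjusted p = 0.02, 0.089 without the 5 arrays, 0.002 to 0.16 over the alternatives) and Ccng1 (2090 against 4400, -1.07 ± 0.22, adjusted p = 0.0013, 0.00026 to 0.094 over the alternatives) were lower. The call of Ccng1 was lost with the mean of its 3 probe sets (0.094), of which 1 passed (adjusted p = 0.0031, 0.54 and 0.34 over probe sets). In the list 7 of 32 were lower and 2 higher, the same numbers adjusted over the list alone, and the list was not called (adjusted p = 0.65). Mdm2 read 570 against 983 (-0.79 ± 0.53, adjusted p = 0.37, 0.016 without the 5 arrays, 0.016 to 0.71 over the alternatives).

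Limma called 3202 genes between untreated knockout and wild-type cells, 1413 higher and 1789 lower in the knockout, 1838 by over 2-fold and 175 with both groups below background. The groups were separated in 29.3% of genes, where chance gives 10%. The fit without the 5 arrays called 3781 genes, 1816 higher and 1965 lower, 2715 of them shared. With equal array medians, which moved the median of all genes by 0.222, 2297 were higher and 1277 lower. With only the 6 compared arrays 1258 were called. The probe sets of 4 genes, Asxl2, Atp2c1, Gnpda2 and H13, passed in opposite directions.

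Between the untreated line R and the untreated knockout, single genes for secreted factors and lipid synthesis were lower. The acute phase protein gene Hp was at least 19.5-fold lower (20.7 against 943). The matrix proteases Mmp2 (64.7 against 1560, -4.59 ± 0.37) and Mmp3 (148 against 1420, -3.26 ± 0.31) were lower. So was Ptgs2, which encodes a cyclooxygenase (586 against 2510, -2.10 ± 0.43, adjusted p = 0.0086, 0.081 without the 5 arrays, 0.00024 to 0.34 over the alternatives). Inflammatory and secreted factors were lower as a list (median -0.74, 5 of 29, 10 lower and 2 higher adjusted over the list alone, adjusted p = 4.8e-06), a call lost with an estimated correlation (0.069). Cholesterol synthesis was lower (-0.50, 5 of 20, 10 adjusted over the list alone, adjusted p = 1.2e-08), a call lost in the same way (0.11), with squalene synthase (Fdft1) at 2780 against 5780. Glycolysis genes were lower too (-0.34, 2 of 12, 4 adjusted over the list alone, 0.069 with an estimated correlation). Interferon-stimulated genes were higher (0.56, 6 of 36, 11 higher and 1 lower adjusted over the list alone, adjusted p = 0.00014, and adjusted p = 0.23 with an estimated correlation). The RNA sensor genes Ifih1 (348 against 105, 1.73 ± 0.34) and Ddx58 (874 against 453) were among them. In the PI3K and AKT pathway list 2 of 19 genes were higher and 1 lower, the same adjusted over the list alone (list adjusted p = 0.29). Rptor, a subunit of the mTOR complex that promotes growth, was 0.82 ± 0.19 higher (adjusted p = 0.022, 5.9e-05 to 0.58 over the alternatives, the highest with the mean of all probe sets) and Tsc2, an inhibitor of that complex, 0.67 higher (adjusted p = 0.031, 0.064 without the 5 arrays, 0.0034 to 0.48 over the alternatives). Cdkn1a (-1.03 ± 0.39, adjusted p = 0.17, 0.028 without the 5 arrays, 0.028 to 0.51 over the alternatives) and Ccng1 (0.05, 0.96) did not pass. Of 11 genes named for this comparison as past the threshold, 7 passed with the mean of all probe sets, 9 without the 5 arrays and 2 on the compared arrays only. The ranges over the alternatives were 4.9e-07 to 0.15 for Hp, 2e-04 to 0.25 for Fdft1, 0.0011 to 0.29 for Ifih1 and 0.0029 to 0.3 for Ddx58, and the mean of all probe sets gave 0.12 for Fdft1 and 0.072 for Ddx58.

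Limma called 690 genes between the untreated line R and the knockout, 396 higher and 294 lower in the line labelled R, 342 by over 2-fold and 39 with both groups below background. In all, 17.5% of genes were separated, where chance gives 10%. With the 5 arrays left out 693 genes were called, 358 higher and 335 lower, 433 of them shared. The count was 362 and 369 without replicates 0 and 1 of the untreated knockout, and 430 and 352 without replicates 1 and 2 of the untreated line R. It was 16 with only the 6 compared arrays, and with equal array medians 207 were higher and 286 lower.

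The untreated line R differed from the wild type in 3418 genes, 1709 higher and 1709 lower. Rps4l, a paralog of a ribosomal protein gene, was at least 142-fold lower (4.38 against 6850), Upk3b at least 339-fold and the prostacyclin synthase gene Ptgis at least 117-fold. Rpl39l was at least 161-fold, Hoxc8 at least 80.5-fold and Zic1 at least 44.3-fold higher. Inflammatory and secreted factors were lower (median -1.09, 13 of 29 lower and 2 higher, also adjusted over the list alone, adjusted p = 0.00024), a call lost with an estimated correlation (0.25). Among them were Mmp3 (148 against 8490, -5.84 ± 0.31) and Igfbp3, a binding protein of insulin-like growth factors (-6.59 ± 0.55). Interferon-stimulated genes were higher (0.87, 11 of 36 higher and 1 lower, 12 and 1 adjusted over the list alone, adjusted p = 0.00038, lost with an estimated correlation at 0.33), with Ifit1 at 434 against 51.1. Homologous recombination genes were higher (0.55, 9 of 17 higher and 1 lower, 11 and 1 adjusted over the list alone, adjusted p = 0.00038, lost with an estimated correlation at 0.055), with Exo1 1.16 ± 0.15 higher. Cdkn1a (115 against 592, -2.36 ± 0.39, adjusted p = 0.00015) and Ccng1 (-1.03 ± 0.22, adjusted p = 0.0019, 0.00027 to 0.12 over the alternatives) were lower. The call of Ccng1 was lost on the compared arrays only (0.12) and with the mean of its probe sets (0.083). Mdm2 was not past the threshold (-1.16 ± 0.53, adjusted p = 0.15, 0.0023 without the 5 arrays, 0.0023 to 0.44 over the alternatives). Of the 3418 genes 1918 differed by over 2-fold and 174 lay below background in both groups. In all, 28.7% of genes were separated, where chance gives 10%. With the 5 arrays left out 3941 were called, 2057 higher and 1884 lower, with 2920 shared. With equal array medians, which moved the median of all genes by 0.123, 2084 were higher and 1321 lower. With only the 6 compared arrays 1127 were called. The probe sets of 3 genes, H13, Srpk2 and Tmem30a, passed in opposite directions.

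Some genes that differed between the untreated knockout and wild type changed back in the line labelled R, in which per the labels PKBalpha was put back. Actg2, a smooth muscle actin, differed by 4.22 between the knockout and the wild type and by -3.15 between the line labelled R and the knockout, and by 1.07 between the line labelled R and the wild type (adjusted p = 0.2). Gsta4, a glutathione transferase, differed by -5.27, 1.64 and -3.63 in the same order. Between the line labelled R and the knockout the adjusted p was 0.0022 for Actg2 and 0.0093 for Gsta4 (9.1e-05 to 0.22 and 0.00013 to 0.3 over the alternatives). Of the 3202 genes, 266 (8.31%) changed back, 91 that were higher and 175 that were lower in the knockout, where 61.8 would at random. A further 92 moved in the same direction again, where 59.7 would at random. Of the 266 genes, 75 still differed from the wild type and 191 were not past the threshold against it. Both contrasts share the untreated knockout arrays. With R against the knockout taken from the arrays at 4 h or at 24 h the counts were 199 and 307, against 54.8 and 86.4 at random. The random numbers are for independent lists, while both contrasts hold the knockout line, whichever arrays are taken. A gene whose level is particular to that line would change back in any other, so these counts cannot show an effect of PKBalpha. Akt1 was also not at the wild-type level in the line labelled R. The count was 262 without the 5 arrays, and 6 when each contrast was fitted to its own arrays only. It was 141 and 147 without replicates 0 and 1 of the untreated knockout, and 167 and 132 without replicates 1 and 2 of the untreated line R.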

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

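Of the tests in this part, those of RNA quality, of the loss of PKBalpha, of members already low in untreated knockout cells and of pyruvate carboxylase were chosen only after the result was seen. The results below stand apart because a test of the difference between the responses of 2 lines passed its threshold, or because an array's Gapdh ratio lay apart from those of the other arrays. The list values are medians over the members, called with the preset correlation.

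In the knockout against the wild type at 4 h, p53 targets differed by -0.69. Of 100 drawn splits 1, the real one, gave a size of 0.69 (highest other 0.64). With labels split in both lines, a share under 0.05 argues only against no response in either. It cannot exclude chance, since the list was chosen because its test passed. RNA quality as the whole cause is argued against, since without the 5 arrays of high Gapdh ratio the median was -0.84 (quartiles -1.31 to -0.41, against -1.03 to -0.39 with all arrays), with a rotation test p of 8.4e-06 against 0.00019. A pull of dim genes is argued against as well, since the 25 of 32 members that reached a level of 200 had a median of -0.67 (p = 0.00081 with an estimated correlation). Loss of PKBalpha may be the cause but cannot be told apart from other differences between the lines, because the list differed by -0.58 in the line labelled R too, in which Akt1 was not at the wild-type level, and each genotype was 1 line.

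Cholesterol synthesis differed by 0.83 between the knockout and the wild type at 4 h. Of 100 drawn splits 6 gave a size as large, the highest other 0.98, so this count does not exclude chance, but the other 5 kept the wild-type groups whole, as labelled or exchanged, and so carried the fall of the wild-type line itself. RNA quality as the whole cause is argued against, since without the 5 arrays the median was 0.67 (quartiles 0.49 to 0.87, against 0.66 to 1.07). The rotation test p was 0.0043 against 0.00018. In that fit the calls of this difference and of the wild-type fall were both lost with an estimated correlation. A part for RNA quality is therefore not excluded. Scaling is argued against by medians of 0.84 after quantile normalization and 0.78 with equal array medians. A floor from members already low in the untreated knockout is argued against, since 1 of 20 was lower there by 0.4 or more.

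The log2 Gapdh ratios of the 5 arrays were -0.137 (replicate 2 of untreated wild-type cells), -0.187 (replicate 0 of wild-type cells at 4 h), -0.163 (replicate 2 of the untreated knockout), 0.003 (replicate 1 of the untreated line R) and 0.16 (replicate 2 of the line R at 24 h). RNA broken before labelling may be the cause, but 18 of the 22 other arrays reached the lowest transferrin receptor ratio among the 5 (0.88), which rests on 1 array, the untreated knockout, while the other 4 of the 5 (up to 2.63) exceeded all 22 (0.49 to 1.31). The pyruvate carboxylase ratios were 2.31 to 3.57 on the 5 arrays and 0.59 to 1.7 on the others. Hybridisation is argued against by the hybridisation controls, whose ratios differed by -0.02 (standard error 0.038, 0.15 to 0.36 on the 5 arrays against 0.16 to 0.46). Broken RNA and labelling cannot be told apart, because 0 of the bacterial labelling controls lay above background, and no biological explanation was tested.

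Other lists in the knockout against the wild type at 4 h differed by -0.48 (G2/M genes, adjusted p = 0.11 with an estimated correlation), -0.25 (homologous recombination, 0.078), -0.22 (break sensing and end joining, 0.078), 0.31 (fatty acid synthesis, 0.0042), -0.29 (ATF4 and amino acid response, 0.38), 0.29 (TGF-beta targets, 0.21) and 0.31 (lysosome, 0.23). At 24 h they differed by -0.4 (p53 targets, 0.14), 0.32 (cholesterol synthesis, 0.46), 0.27 (fatty acid synthesis, 0.031), -0.18 (ATF4, 0.72) and 0.15 (unfolded protein response, 0.14). In the line labelled R against the knockout the differences at 4 h were -0.13 (G2/M genes, 0.91), 0.22 (glycolysis, 0.5), 0.32 (hypoxia targets, 0.5), 0.13 (ATF4, 0.91) and 0.1 (ribosomal proteins, 0.91). At 24 h they were -0.21 (S phase and E2F genes, 0.72), -0.16 (homologous recombination, 0.44) and 0.25 (HOX genes, 0.44). In the line labelled R against the wild type the differences at 4 h were -0.58 (p53 targets, 0.051), -0.65 (G2/M genes, 0.042), -0.35 (homologous recombination, 0.013), 0.75 (cholesterol synthesis, 0.013), 0.37 (fatty acid synthesis, 0.0015), 0.2 (inflammatory and secreted factors, 0.5) and 0.19 (lysosome, 0.3). At 24 h they were -0.18 (p53 targets), 0.2 (extracellular matrix), -0.15 (ribosomal proteins, mean 0) and -0.12 (oxidative phosphorylation), each with 0.74. In R against the wild type at 4 h, 2 of 100 splits gave the p53 list a size of 0.58 or more (highest other 0.64). This share, under 0.05, has the limits given above.

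Among single genes, C430042M11Rik differed by -5.53 (adjusted p = 0.025) and D630004K10Rik by -3.14 (0.0055) in the knockout against the wild type at 4 h, and D630004K10Rik by -3.05 at 24 h (0.0083). Ang3 differed by 7.57 in the line labelled R against the knockout at 24 h (0.023). In these 4 results all 4 groups lay below background. Between the line labelled R and the wild type D630004K10Rik differed by -3.88 at 4 h (0.00021) and -3.05 at 24 h (0.0086), with 49.3 in the untreated line R and 2.63 in untreated wild-type cells. Nkd1 differed by 3.04 (0.012) and Sorbs2 by -3.21 (0.022) at 4 h. With levels below background set to it, these last 4 differences were -0.03, -0.03, 2.03 and -2.35.

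The comparisons of 3 arrays with 3 have 10 splits, too few for a share under 0.05. The real counts and the highest of the other splits were 592 and 6 (wild type at 4 h), 9 and 6 (24 h), 67 and 3 (knockout at 4 h), 178 and 3 (line labelled R at 4 h), 3202 and 3 (untreated knockout against wild type), 690 and 2 (untreated line R against knockout) and 3418 and 1 (untreated line R against wild type), and in each 1 split, the real one, reached the real count. For the counts of 0 at 24 h in the knockout (1064 at an unadjusted p under 0.05 by limma) and in the line labelled R (830), all 10 splits reached it, as any split must, so these decide nothing (highest others 4 and 1).

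For counts above 0 of genes whose response differed, chance is not excluded. Of 100 drawn splits 12 reached the real count for the knockout against the wild type at 4 h (2, highest other 10) and 34 at 24 h (1, highest other 4). For the line labelled R 28 did against the knockout at 24 h (1, highest other 61), and against the wild type 9 at 4 h (3, highest other 1721) and 28 at 24 h (1, highest other 86). Against the knockout at 4 h the real count was 0 (537 unadjusted by limma), which all 100 splits must reach, so this decides nothing (highest other 146). The split with 1721 exchanged the untreated and 4 h arrays of the line labelled R alone and so measured the sum of both responses, and that with 146 exchanged those of the knockout and mixed those of the line labelled R. Those with 61 and 86 placed the 2 arrays of the line labelled R with a high Gapdh ratio in 1 group, a structure of the samples. For the 266 genes that changed back in the line labelled R, 2 of 100 splits reached the count, a share under 0.05, but the other one called 1272 and placed the 3 untreated arrays of high Gapdh ratio in 1 group, which points to the same structure. Without the 5 arrays the count was 262.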

How the results depend on the processing

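The Gapdh covariate, the fit without the 5 arrays of high Gapdh ratio, the offset of 32 and the correlations above the median level without those arrays were tests chosen only after the results were seen. Of 170 results for genes named in the text, 88 kept their side of the threshold under each alternative that gave a value. Of the 112 past the threshold 39 stayed past it under every alternative and 73 lost their call in at least 1, among them each of the 23 and 5 in the wild type at 4 h and 24 h, the 11 in the knockout at 4 h and the 12 in the line labelled R at 4 h. Of 122 called lists 23 did, 93 lost their call with an estimated correlation (29 remained), 41 with the mean of all probe sets, 26 on the compared arrays only, 20 above the median level, 17 with equal array medians, 14 without the 5 arrays, 11 after quantile normalization, 8 with the covariate, 5 with the offset, 2 with a replicate block and 0 with an intensity trend. S phase and E2F genes in the line labelled R at 24 h (-0.08) reversed to 0.06 and 0.03 without replicate 0 of its untreated cells and replicate 2 at 24 h (range -0.21 to 0.06 with single arrays left out), and ribosomal proteins there (-0.12) to 0.01 after quantile normalization. Where counts of genes moved by over 1.5 times, they are given below, and the cause was not tested.

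On the compared arrays only, which leaves fewer arrays for the spread, the counts were 0 in the wild type at 4 h (2081 unadjusted by limma) and 24 h (1139), 0 at 4 h in the knockout (2358) and in the line labelled R (1782), 1258, 16 and 1127 between untreated lines (knockout against wild type, R against knockout, R against wild type), and 6 for genes that changed back. Response differences gave 1 for the knockout against the wild type at 4 h and 0 at 24 h (637), 0 for R against the knockout at 24 h (565), and 6 and 2 for R against the wild type. With an intensity trend the counts were 19 (wild type at 24 h), 185 and 1 (knockout at 4 h and 24 h), 336 and 1 (R), and 0 for the differences between knockout and wild type at 4 h (1010) and 24 h (572) and between R and wild type at 24 h (659). Above the median level, where fewer genes were tested, they were 1152 and 18 (wild type), 317 and 1 (knockout), 618 and 2 (R), 0 between knockout and wild type at 4 h (511) and R and knockout at 24 h (76), and 2 between R and wild type at 24 h. Quantile normalization gave 40 (knockout at 4 h), 1 (R at 24 h), and 4 and 2 (knockout against wild type). Equal array medians gave 346, 20 and 35 at 4 h in the wild type, knockout and R, and 8 for the difference between R and wild type at 4 h, and moved the median of all genes by over 0.1 in 7 contrasts (0.131, 0.222, 0.123, -0.127, -0.107, -0.102 and -0.156). The mean of all probe sets gave 278 and 1 (wild type), 22 (knockout at 4 h), 37 (R at 4 h) and 1 (R against wild type at 4 h). Every probe set tested gave 363 and 1 (wild type), 8 and 33 (knockout and R at 4 h), 1 (knockout against wild type at 4 h), and 1 and 0 (1380) for R against the knockout. A replicate block gave 1 (knockout at 24 h), 1 (knockout against wild type at 4 h) and 2 (R against knockout at 24 h). The Gapdh covariate gave 1942 and 25 (wild type), 314 (knockout at 4 h), 443 and 4 (R), 1327 (untreated R against knockout), 510 that changed back, 8 and 28 for response differences at 4 h against the wild type (knockout, R), and 0 (634) for R against the knockout at 24 h. Without the 5 arrays they were 366 (wild type at 4 h), 166 and 6 (knockout), 80 and 1 (R), 19 and 0 (932; knockout against wild type), 4 (R against knockout at 24 h), and 9 and 3 (R against wild type). The offset gave 139 and 1 (knockout), and 0 at 24 h for each response difference (642, 505 and 749).

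Correlations of responses (knockout and wild type, R and knockout, R and wild type) were 0.15, 0.18 and 0.14 at 4 h and 0.1, 0.04 and 0.06 at 24 h. They were 0.69, 0.84, 0.69, 0.64, 0.46 and 0.37 above the median level, 0.53, 0.76, 0.52, 0.42, 0.4 and 0.3 there without the 5 arrays, and 0.48, 0.61, 0.48, 0.37, 0.22 and 0.2 with the offset. Over genes past the threshold in 1 or both lines they were 0.56, 0.7, 0.52, 0.64 and 0.41. Those at 24 h used the 9 genes called in the wild type, with no value for R and knockout. Without the 5 arrays they were 0.09, 0.12, 0.08, 0.05, 0.03 and 0.04. With single arrays left out they ran from 0.1 to 0.15, 0.12 to 0.19, 0.09 to 0.15, 0.05 to 0.11, 0 to 0.07 and 0 to 0.09. The counts ran from 190 to 481 and 3 to 23 (wild type), 0 to 18 and 0 to 6 (knockout), 11 to 388 and 0 to 2 (R), 2505 to 3080, 352 to 596 and 2714 to 3329 (untreated lines), 132 to 256 (changed back), and 109 to 127 called lists. Response differences ran from 1 to 8 and 0 to 6 (knockout against wild type), 0 to 2 and 0 to 2 (R against knockout), and 1 to 6 and 0 to 4 (R against wild type). Signal over background limits the dim genes, whose median SD of 1.44 in the dimmest 10% compares with 0.18 in the brightest 10%, and 10577 to 11682 genes per array lay above background.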

Other observations

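Further lists passed the test with the preset correlation and are given as values. In wild-type cells at 4 h heat shock genes had a median of 0.37 (1 of 13 higher, 4 adjusted over the list alone, adjusted p = 0.028 with an estimated correlation) and unfolded protein response genes of -0.25 (1 of 16 lower, 4 adjusted over the list alone, 0.023). Mesenchymal fibroblast markers had a median of -0.15 (2 of 13 lower, 3 adjusted over the list alone, 0.032). Ribosome biogenesis genes had a median of 0.4 (3 of 21 higher, 10 adjusted over the list alone, 0.095) and interferon-stimulated genes of -0.4 (2 of 36 lower, 4 adjusted over the list alone, 0.25).

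In the knockout at 4 h ATF4 and amino acid response genes had a median of -0.34 (21 of 22 negative, 6 lower adjusted over the list alone, none over all genes, 0.17 with an estimated correlation). Hypoxia targets had a median of -0.51 (13 of 14 negative, 4 lower adjusted over the list alone, none over all genes, 0.079). In the line labelled R at 24 h 33 of 36 interferon-stimulated genes had a positive difference (median 0.32, none called, 0.34). In untreated knockout against wild-type cells 7 of 16 NRF2 targets were lower (7 lower and 1 higher adjusted over the list alone, median -0.23, 0.35).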
